A study of Mus musculus with 8 samples.

How the data were processed

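RNA-seq was performed on left ventricles of 12-week-old C57BL/6 mice of 2 genotypes, with 4 animals per genotype and 2 per sex within each. The control animals carry the genotype label wild-type and are titled NLC. The KO animals are labelled as lacking ADGRF5, also called GPR116, in cardiomyocytes. Groups, sexes and replicate numbers were taken from the titles and characteristics. Per the labels' protocols, total RNA was isolated with a column kit and stranded mRNA libraries were made with a TruSeq kit and sequenced with HiSeq rapid kits.

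The deposited files hold raw read counts per gene, one file per library, with 55487 Ensembl gene identifiers and 5 summary entries each. Per the submitters' processing notes, STAR, HTSeq and DESeq2 were used with the mouse build GRCm38. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here. The summary entries name no gene and were kept out of library sizes and tests. Of all tallied reads they held 16.8% to 20.3% as multiply mapped, 3.07% to 4.08% outside genes and 1.26% to 1.38% as ambiguous. Reads shared between near-identical copies are therefore mostly uncounted, which lowers the values of such genes. Because the strand setting is not known, reads of a gene and of an overlapping gene on the opposite strand may not be separated.

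Symbols and coordinates came from the GENCODE M21 annotation of GRCm38, in which 55141 identifiers had a symbol. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr by genotype, which left 14695, and libraries were scaled by TMM factors. The KO against control comparison was a quasi-likelihood test (glmQLFit and glmQLFTest) with sex as an additive term. Contrasts within males, within females and their difference came from a fit with 1 mean per sex and genotype. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05 and no fold minimum. Normalised values are CPM, computed with TMM-scaled library sizes, and fold changes are log2 of KO over control with their standard errors (SE).

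The group design, the tests, the 41 gene lists and the rule for named genes were fixed before the data were examined. The rule named Adgrf5, and up to 14 called genes per direction with a mean of at least 1 CPM, the same direction in both sexes and no predicted or clone symbol. One such gene is not reported here. For the sex contrasts it named up to 5 called genes per direction. For each called list and 7 lists of prior interest it named up to 4 members with the smallest p. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with an estimated correlation and with fry beside it. A list score is the mean log2 CPM of the members in a library, each member centred on its mean over the 8 libraries. The mean log2 change of a list averages the members' coefficients in a linear fit to the log2 CPM. It can differ from the mean of their edgeR log2 fold changes, over which the list medians are taken. Adgrf5 was also tested by an exact two-sided permutation test over all 70 assignments of 4 and 4 libraries.

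The fits were tested on simulated counts drawn from the means, dispersions and library sizes of the 14695 genes. In each of 5 simulations 200 genes were changed, all taken from those with a mean of at least 1 CPM. For KO against control, 56.7% of genes changed 1.5-fold, 88.7% changed 2-fold and 97.6% changed 3-fold were recovered. False calls made up 7.33% of the calls. With the change placed in males alone, 3-fold changes were recovered in 93.6% of cases by the male contrast and in 77.3% by the sex by genotype interaction. Camera called 0 lists in 5 simulations without a change, and the p53 target list in 5 of 5 when its members were raised 1.5-fold. These simulations draw genes independently, so they leave out correlation between genes. The recovered shares hold for 200 changed genes at 1 CPM or more, and fewer changed genes make the adjusted threshold harder to reach.

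Alternatives comprised DESeq2 1.42.0, limma voom with and without sample quality weights, other scalings, removal of mitochondrially encoded genes, no filter or a stricter one (at least 1 CPM in 4 libraries), a fit without sex, a replicate block, 1 surrogate variable (sva 3.50.0), a threshold of 0.1, and each library left out in turn. A fit with the atrial list score as a covariate and a fit without control replicates 3 and 4 were added after the data were seen. No library was left out of the results given first. A count of 0 allows a level of up to 0.0757 to 0.118 CPM (3 counts per library), a bound that covers counting error only.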

Results

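Gene expression was measured in the left ventricles of 8 mice at 12 weeks of age. In all, 4 control animals and 4 animals labelled KO were compared, with 2 males and 2 females in each group. ADGRF5 is an adhesion G protein-coupled receptor, and the title of the series places it in cardiac homeostasis through Gαq. The comparison asks which ventricular transcripts change when cardiomyocytes lack the receptor. The libraries held 27.33, 25.33, 28.35 and 28.04 M gene reads in control replicates 1 to 4 and 39.62, 28.81, 28.00 and 26.59 M in KO replicates 1 to 4. Mitochondrially encoded genes took 17.4% to 21.9% of these reads. Replicates 1 and 2 of each group were male and replicates 3 and 4 female. Xist stood at 148.1 to 180.9 CPM in the 4 female libraries and at 0.138 to 0.337 CPM in the 4 males, while Ddx3y stood at 41.95 to 60.21 CPM in males and at 0 to 0.0675 CPM in females. No pair of libraries within a group was alike within sampling noise, with a chi-square per degree of freedom of 15.3 to 41.7.

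The targeted gene, Adgrf5, was as abundant in the libraries labelled KO as in the controls. It was measured at 233 ± 17.4 CPM in controls and 224 ± 15.7 CPM in KO (SD, n = 4 each). Single libraries lay at 233.3, 257.0, 222.3 and 218.2 CPM in controls and 223.2, 230.9, 203.0 and 239.8 CPM in KO. The log2 fold change was -0.05 (SE 0.0754, edgeR adjusted p = 0.782), and its 95% interval ran from a change of -14.1% to 8.35%. An exact two-sided permutation test gave p = 0.514, where the smallest reachable p was 0.0286. Adgrf5 (ENSMUSG00000056492) spans 43360451 to 43459557 on chromosome 17 of GRCm38. Endothelial cells also transcribe this gene, and counts cover the entire gene, so the level in whole ventricle does not check the genotype labels, and every direction given here rests on them.

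The 12 genes named here set KO ventricles apart from controls, of which 5 rose and 7 fell. Dmd, which encodes dystrophin, the protein that ties the cytoskeleton of muscle cells to their membrane, fell from 79.0 ± 8.14 to 36.0 ± 12.5 CPM (log2 fold change -1.19, SE 0.154). Ctnna3, the αT-catenin of the intercalated disc, fell from 21.04 ± 2.13 to 11.2 ± 2.45 CPM (log2 fold change -0.93, SE 0.118). Phlda3, a p53 target whose product restrains Akt, rose from 14.9 ± 2.54 to 26.7 ± 2.48 CPM (log2 fold change 0.85, SE 0.106). In total 15 of 14695 genes passed (7 higher, 8 lower), and their edgeR adjusted p-values ranged from 0.0131 to 0.0460.

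Among these, Ppp2r3a, a regulatory subunit of protein phosphatase 2A, was the most abundant gene that fell, at 285 ± 40.5 CPM in controls and 149 ± 20.7 CPM in KO. Exoc2, a component of the exocyst complex, fell from 20.96 ± 0.646 to 13.1 ± 0.786 CPM with an adjusted p of 0.0186 by edgeR. Rps6ka2, which encodes the kinase RSK3, changed by -0.62 (SE 0.0923) and Ssbp2, a single-stranded DNA-binding protein, by -0.68 (SE 0.0967) on the log2 scale. Klhl34, a kelch-like gene on the X chromosome, changed by -1.05 (SE 0.143). The genes that fell included some of the longest in the genome. Dmd spans 2257.3 kb at 82948870 to 85206141 on chromosome X, and Ctnna3 spans 1573.6 kb at 63430098 to 65003667 on chromosome 10.

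Of the genes that rose, Rom1, a tetraspanin known from photoreceptor discs, had the smallest p. It lies at 8927391 to 8929356 on chromosome 19 and moved from 20.4 ± 1.101 to 33.0 ± 1.54 CPM (log2 fold change 0.69, SE 0.0714, edgeR adjusted p = 0.0131). Klhdc7a, a kelch-domain gene, rose by 1.16 (SE 0.141) on the log2 scale. Rtn4r, the Nogo receptor, rose by 1.07 (SE 0.153), and Epn3, an epsin of clathrin-mediated endocytosis, rose by 0.78 (SE 0.103). A further 2 called genes fall outside the naming rule and were picked out after their values were seen. Maats1 (38297754 to 38342143 on chromosome 16) was nearly absent from controls, with 7 reads over the 4 libraries, and had 135 reads in KO, a 17.6-fold difference in mean CPM with a counting interval of 8.21 to 44. 1700120C14Rik rose by 0.82 on the log2 scale. It overlaps Mcrs1 on the opposite strand, and Ctnna3, Dmd, Ssbp2, Ppp2r3a and Maats1 also overlap annotated opposite-strand genes, so their counts carry that uncertainty.

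For all 12 named genes the 4 KO libraries lay on one side of the 4 controls, which their selection by the test largely fixes. Of all tested genes 6.25% showed such a separation, against 2.86% by chance. The number of calls rested on single libraries. It was 0 without control replicate 1, control replicate 2, KO replicate 2 or KO replicate 3, 4 without KO replicate 1 or 4, and 50 without control replicate 3, although no named gene changed direction in any of these fits. Each of the 12 named genes passed in only 1 to 4 of the 8 fits that left out a library. Over 22 alternative settings they kept their call in 8 (Rps6ka2) to 17 (Rom1). DESeq2 called 140 genes, among them all 15.

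**Figure D1:**
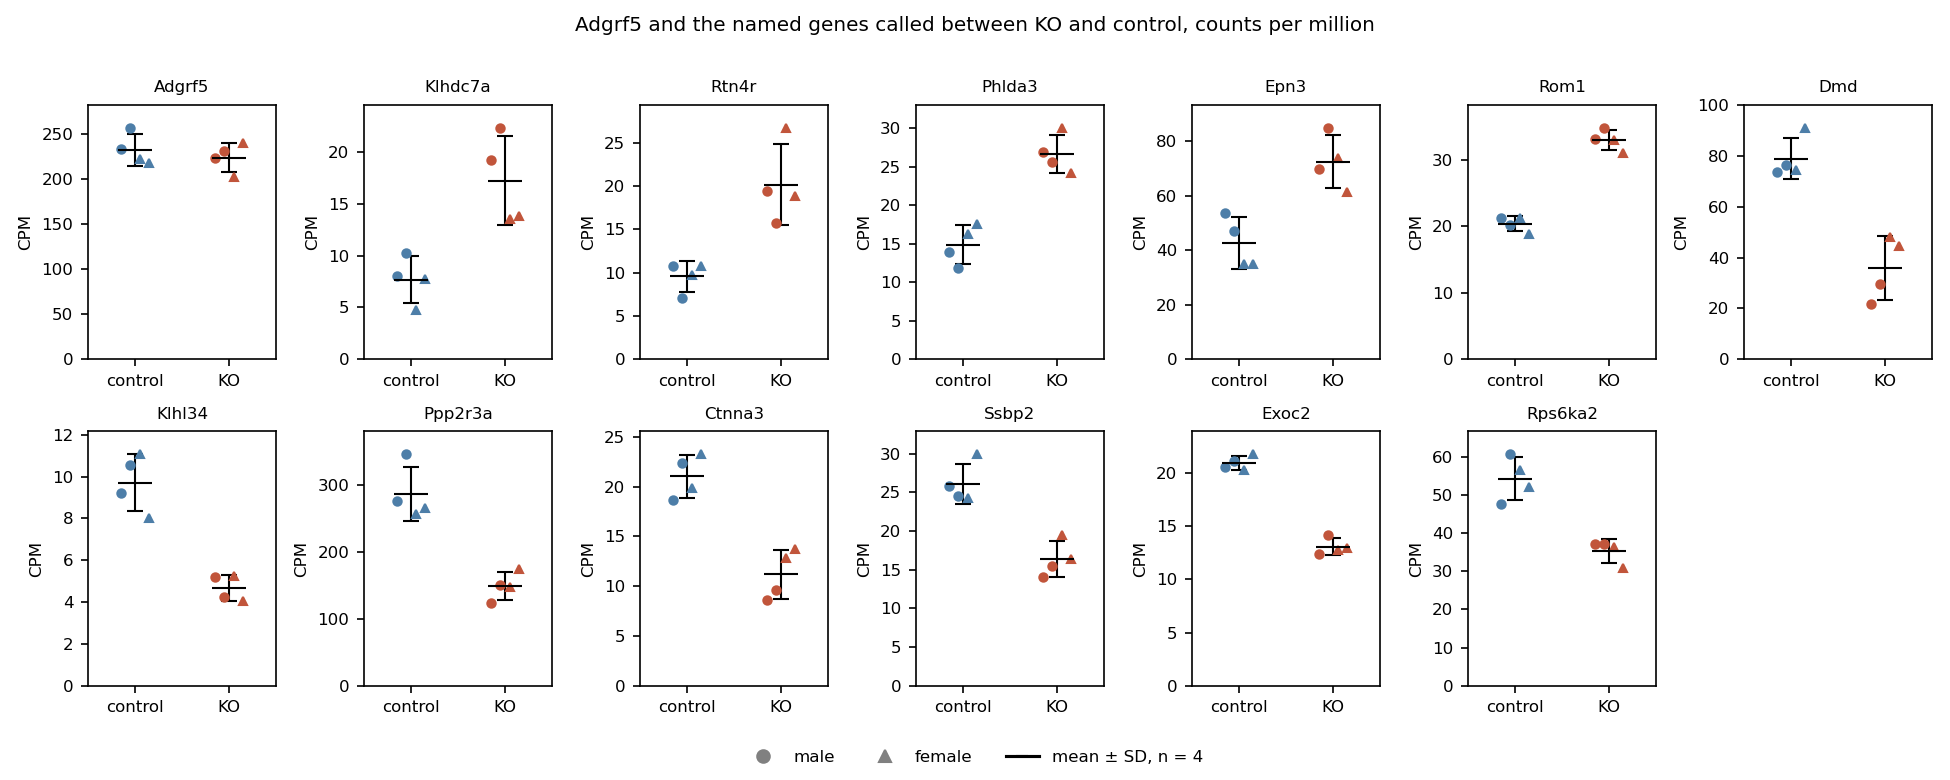
Normalised counts in CPM (vertical axes, from 0) of Adgrf5 and the 12 named genes in the 4 control and 4 KO libraries, with circles for males, triangles for females and bars for the mean ± SD. The groups overlap for Adgrf5 (233 against 224 CPM) and do not overlap for any of the 12 named genes.

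Gene groups were then compared, using the 41 lists. At the preset correlation camera called 13, of which 6 were higher and 7 lower in KO. With an estimated correlation, or by the directional fry test, 0 passed. The mixed fry test asks for changes in either direction. Of the called lists it passed fast skeletal muscle (adjusted p = 0.000276), p53 targets (0.00209), glycolysis (0.0128), endothelial markers (0.0291) and the stress response (0.0482). The other called lists did not pass it (0.161 to 0.561). It also passed cholesterol synthesis (0.0016), autophagy and lysosome (0.0137) and Gq signalling (0.0452), which camera did not call. p53 targets were among the higher lists. Of 21 measured members 14 had a positive log2 fold change, and 1 rose over all genes tested. Adjusted over the list alone, 3 rose, namely Phlda3, the cell cycle inhibitor Cdkn1a (0.65, SE 0.169) and the nuclease gene Aen (0.31, SE 0.0793), while Casp12 stood at -0.49 (SE 0.197). Camera gave this list an adjusted p of 0.0435, and adjusted p = 0.880 with an estimated correlation. The 4 KO libraries scored 0.01 to 0.122 and the 4 controls -0.092 to -0.022. Such a separation was not particular to p53 targets. The glycolysis list (KO -0.027 to 0.106, controls -0.038 to -0.03) and the fast skeletal muscle list (KO 0.168 to 0.573, controls -0.566 to -0.026) also separated. Leaving out control replicate 1, 3 or 4 or KO replicate 2 or 3 raised the adjusted p to between 0.0675 and 0.145.

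Lists of energy metabolism, contractile genes and a stress response formed the rest of the higher group. The adjusted camera p was 0.0173 for glycolysis and for oxidative phosphorylation, 0.0397 for sarcomere genes, 0.0397 for the integrated and mitochondrial stress response and 0.0086 for fast skeletal muscle transcripts. With an estimated correlation the adjusted p was 0.815 for the fast skeletal muscle list and 0.896 for the other 4. Over all genes tested no member of these lists passed. Adjusted over the list alone, 3 glycolytic genes were higher, namely Hk1 at 0.37 (SE 0.0929), Pfkp at 0.30 (SE 0.0857) and Eno1 at 0.23 (SE 0.0677). In the fast skeletal muscle list 3 of 8 members were higher adjusted over the list alone, including the calcium pump gene Atp2a1 at 1.21 (SE 0.299), while the light chain gene Myl1 was lower at -0.71 (SE 0.235). In the stress response list Mthfd2, a mitochondrial folate enzyme, was higher at 0.93 (SE 0.229) and Vldlr lower at -0.31 (SE 0.0767) by the same measure. Sarcomere genes gave 0 of 24 members either way, with Des at 0.22 (SE 0.0682) and Tnnc1 at 0.27 (SE 0.0985), and oxidative phosphorylation gave 0 of 47, with Ndufa8 at 0.20 (SE 0.0844) and Ndufs1 at -0.18 (SE 0.0905). The fast skeletal muscle list passed without each library in turn. Glycolysis did not pass without control replicate 3 or KO replicate 1 or 4 (adjusted p 0.0542 to 0.0653), oxidative phosphorylation without control replicate 2, 3 or 4 or KO replicate 1 or 4 (0.0683 to 0.222), the stress response without control replicate 1, 3 or 4 or KO replicate 1 or 3 (0.0585 to 0.163), and sarcomere genes without any library but control replicate 1 and KO replicate 2 (0.0651 to 0.143).

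Interferon, antigen presentation and cell cycle lists were called lower in KO, and all 3 were highest in control replicate 3. The interferon response list had a median log2 fold change of -0.32 (camera adjusted p = 0.00051), antigen presentation -0.35 (adjusted p = 0.0086), and cell cycle -0.53 (adjusted p = 0.0173), each with an adjusted p = 0.896 with an estimated correlation. In control replicate 3 these lists scored 0.753, 0.745 and 0.83, whereas the other 7 libraries ranged from -0.223 to 0.086, -0.334 to 0.211 and -0.348 to -0.032. Their mean log2 changes were -0.28, -0.31 and -0.30, and without that library -0.06, -0.06 and -0.05 (adjusted p 0.357, 0.357 and 0.676). Without control replicate 4 the interferon mean was -0.44 and that of antigen presentation -0.49, and without KO replicate 3 the cell cycle mean was -0.20 (adjusted p = 0.163). Interferon-induced Iigp1 (-0.91, SE 0.213) was the only member of these lists that was lower adjusted over the list alone, and the centromere gene Cenpf was higher (0.81, SE 0.174), against the direction of the cell cycle list.

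Branched-chain amino acid breakdown (median -0.13, adjusted p = 0.0086), calcium handling (-0.12, adjusted p = 0.0204), lymphocyte markers (-0.29, adjusted p = 0.0397) and endothelial markers (-0.04, adjusted p = 0.0397) completed the lower lists, all with an adjusted p = 0.896 with an estimated correlation. Dbt, a core subunit of the branched-chain ketoacid dehydrogenase, was lower adjusted over the list alone (-0.36, SE 0.0915), as were the endothelial genes Emcn, Mmrn2, Vwf and Pecam1 at -0.29, -0.24, -0.30 and -0.23. No calcium handling gene passed either way, and Atp2a2, the sarcoplasmic calcium pump, stood at -0.27 (SE 0.102). Atp2b1, Asph and Trdn, the members with the smallest p, span 111.7 to 396.2 kb. The fall of long genes in general, given below, was not separated from that of this list. The calcium list also holds Sln, an atrial transcript. The atrial list score was highest in control replicate 4 (2.395) but graded over the libraries. It was 1.014 in KO replicate 3 and 0.82 in control replicate 2, and lowest in KO replicate 1 (-1.617) and control replicate 3 (-1.659). The mean log2 change of the calcium list was -0.21, and -0.05 with the atrial score as a covariate (adjusted p = 0.126). It was -0.12 without control replicate 4 (adjusted p = 0.0433) and -0.39 without control replicate 3 (0.00119). Sln is also part of the atrial score, and ran from 0.026 CPM in KO replicate 1 to 221.9 CPM in control replicate 4. These shifts can therefore rest on Sln, and the list without Sln was not tested. The calcium list did not pass without control replicate 1 or KO replicate 2 (0.0841 and 0.0729), nor without control replicate 2 or KO replicate 1 (mean -0.13 and -0.11, adjusted p 0.098 and 0.0747). Nor did the branched-chain list pass without KO replicate 2 (0.0666) or with 1 surrogate variable (0.0705). The endothelial list did not pass without control replicate 1 or 3 or KO replicate 2 or 3 (0.0501 to 0.676), nor the lymphocyte list without control replicate 1 or 3 or KO replicate 3 or 4 (0.143 to 0.343). The endothelial mean log2 change went from -0.074 to -0.012 without control replicate 3. The lymphocyte mean went from -0.30 to -0.09 without KO replicate 3.

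Gq signalling, the pathway named in the series title, was not called by camera (median -0.07, adjusted p = 0.0687, and 0.896 with an estimated correlation). The mixed fry test passed the list (adjusted p = 0.0452) and the directional fry test did not (0.470). At an unadjusted edgeR p under 0.05, 7 members were lower and 0 higher. None of the 33 measured Gq members passed over all genes, and Plcb1, a phospholipase C activated by Gq, stood at -0.49 (SE 0.128, edgeR adjusted p = 0.226). The hypertrophy and fetal gene program was not called either (median 0.17, adjusted p = 0.350), with Myh7 at 0.64 (SE 0.176), Gdf15 at 1.22 (SE 0.418), Xirp2 at -0.22 (SE 0.0949) and Ankrd1 at 0.43 (SE 0.210). The hypertrophy list passed without KO replicate 4 (adjusted p = 0.00584) and Gq signalling without control replicate 1 (0.039), without KO replicate 4 (0.0498) or with no low count filter (0.0394). Extracellular matrix genes (median -0.04, adjusted p = 0.231, and 0.0352 or 0.0141 without KO replicate 2 or 3) and the adhesion receptor family (median -0.13, adjusted p = 0.611) did not pass, and the direction of both turned in some settings. Among the adhesion receptors Adgrl2 stood at -0.28 (SE 0.0729), Adgrg1 at 0.24 (SE 0.092), Adgra3 at -0.18 (SE 0.0785) and Adgrb2 at -0.59 (SE 0.282).

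**Figure D2:**
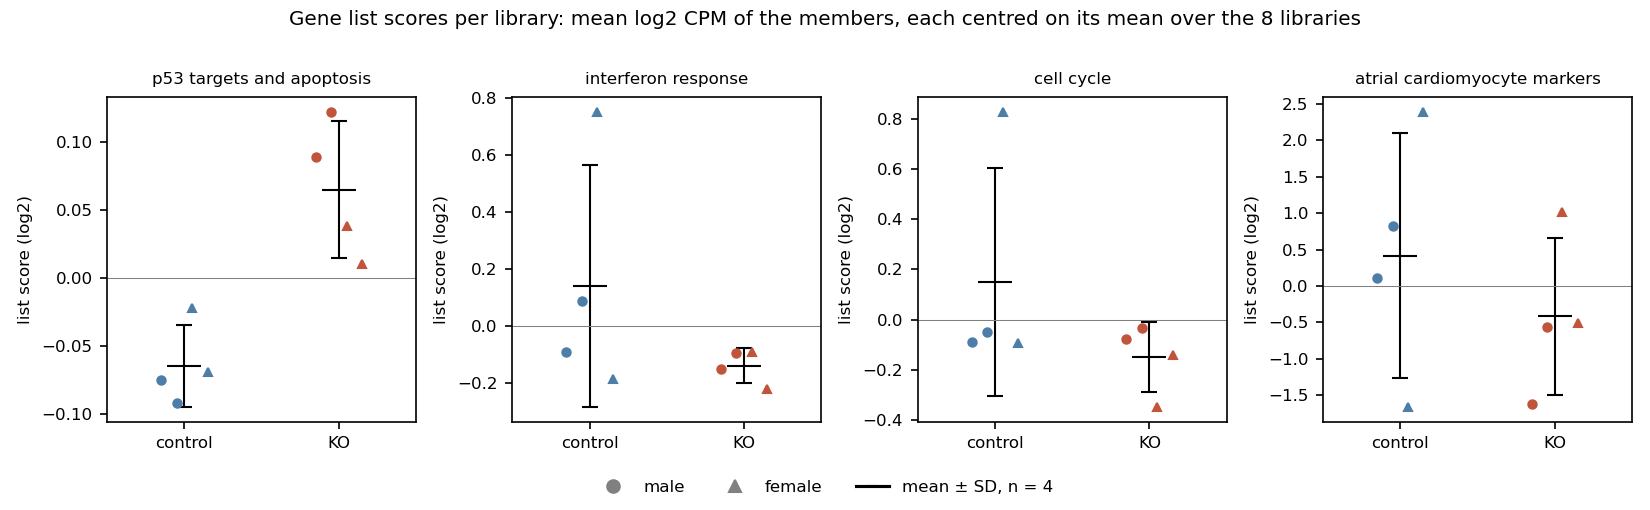
Scores of 4 gene lists per library (vertical axes, log2 scale, members centred on their mean over the 8 libraries), with circles for males, triangles for females and bars for the mean ± SD of 4 libraries. All KO scores for p53 targets (0.01 to 0.122) lie above all control scores, as also holds for the glycolysis and fast skeletal muscle lists, not shown. The interferon and cell cycle lists are high in control replicate 3. Atrial markers are highest in control replicate 4 (2.395), followed by KO replicate 3 (1.014) and control replicate 2 (0.82).

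Within males, 6 genes differed between KO and control. Per1, a core gene of the circadian clock, rose by 1.45 (SE 0.158) on the log2 scale. Cacna1h, the T-type calcium channel Cav3.2, fell by 1.90 (SE 0.184), and Pkia, an inhibitor of protein kinase A, fell by 0.95 (SE 0.113). Dmd fell by 1.56, Ctnna3 fell by 1.17 and Ppp2r3a fell by 1.18 in the same contrast, and the edgeR adjusted p-values of the 6 genes were 0.0167 to 0.0377. Within females 0 genes passed by edgeR (753 at an unadjusted p under 0.05) and 16 by DESeq2. The female log2 fold changes of Dmd, Ctnna3 and Ppp2r3a were -0.83, -0.70 and -0.70. By library number both male KO libraries come before both male controls, whereas in females the groups interleave. Anything that followed this order, such as handling or time of collection, cannot be told apart from genotype in males.

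The difference between the sexes was tested directly and gave 0 genes by edgeR (1096 at an unadjusted p under 0.05) and 18 by DESeq2. Per1 (difference 1.66, male minus female) and Cacna1h (-1.75) each had an adjusted p of 0.363, so a difference between males and females is not shown for either gene. Each sex holds 2 libraries per genotype, and the male count was 0 without control replicate 1, 1 or 2 without control replicate 2 or any KO library, 38 without control replicate 3 and 59 without control replicate 4. Without control replicate 3 or 4 the female count was 39 or 81 and the interaction count 8 or 2, and the interaction count was 1 without control replicate 2.

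**Figure D3:**
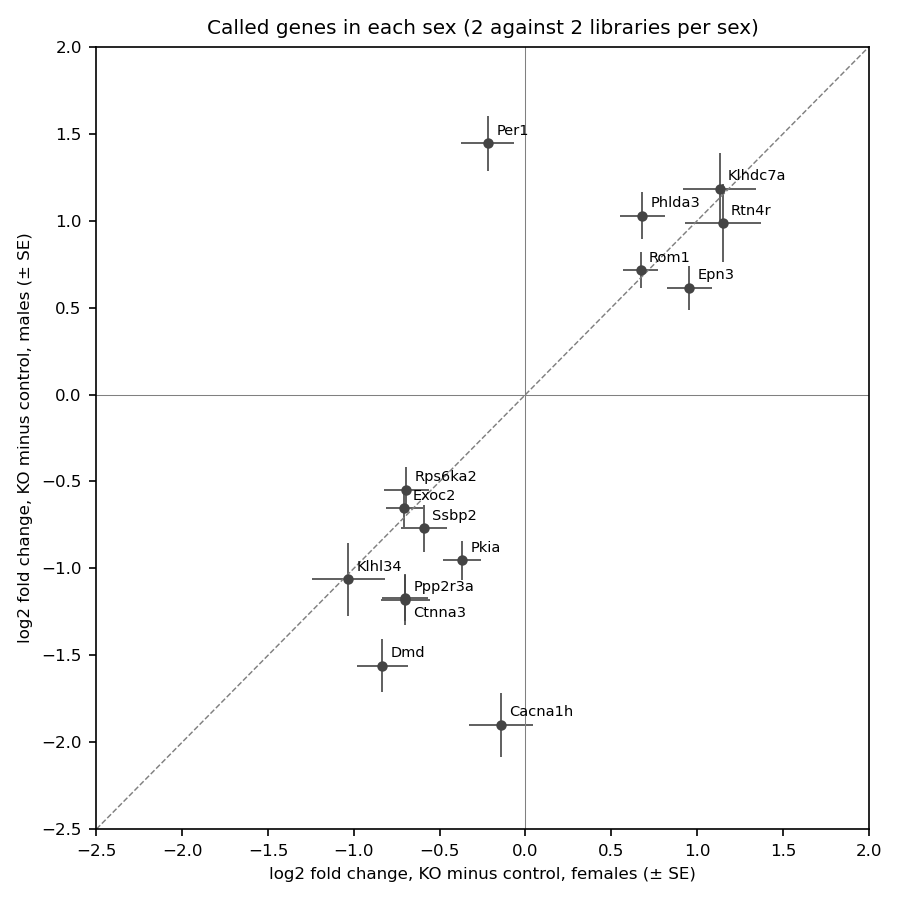
Log2 fold changes, KO minus control, in females (horizontal axis) and males (vertical axis) for the 12 named genes and the further genes called in males, with bars for ± SE and a dashed line of equal change (2 libraries per sex and genotype). Per1 (1.45 in males, -0.22 in females) and Cacna1h (-1.90 and -0.14) lie farthest from the line, with an interaction adjusted p of 0.363 each.

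Males and females differed in 44 genes across both genotypes, 32 higher and 12 lower in males. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher in males, by 9.49 to 10.72 on the log2 scale. Their X-linked relatives Kdm5c (-0.78, SE 0.0617), Kdm6a (-0.99, SE 0.0878) and Eif2s3x (-0.76, SE 0.0910) were lower in males, as was Xist (-9.25, SE 0.163), the RNA that coats the inactive X chromosome. Among autosomal genes Chd6, a chromatin remodeller, was lower in males (-0.73, SE 0.0794), and the pseudogene Vdac3-ps1 was higher (3.13, SE 0.172), a value that is uncertain because it can share reads with its parent gene. All edgeR adjusted p-values of these 10 genes were 0.00686 or below. The count was 16 without control replicate 1, 21 without control replicate 2, 27 without control replicate 4, 23, 27 and 17 without KO replicates 1, 2 and 3, and 176 without control replicate 3.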

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

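The tests for atrial tissue and for a larger library were chosen only after the result was seen. Within groups of 4 libraries, 15 of 278 values set 1 library far from the other 3, and chance gives about 1 in 20.

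Control replicate 4 held high levels of atrial transcripts, with Nppa at 3778 CPM, Myl4 at 1020, Myl7 at 983.4 and Sln at 221.9. It was not the only library with them. Myl7 stood at 182.8 CPM in KO replicate 3 and 156.6 in control replicate 2, against 0.2645 in KO replicate 1 and 0.3711 in control replicate 3. By the rule for outlying values the atrial score of control replicate 4 was not flagged. Its gene reads were 1.001 times the median of the other libraries, which argues against a deeper library. Of 12 measured atrial markers 11 were highest in this library, so atrial tissue in the dissected piece is a candidate explanation. The scores for adipocyte (1.531), epicardial and valve (1.335), nerve (0.568) and conduction markers (0.548) were also highest here and that for red blood cell transcripts (-1.318) lowest, so other tissue or a different dissection stays open. Of the atrial markers 3 are also in another list and 10 reached 1 CPM in control replicate 3, where the atrial score was lowest, and a biological difference of this animal was not tested.

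In controls, replicate 4 stood apart for Dmd (91.05 CPM against 73.88 to 76.53), Atp2a1 (5.083 against 1.451 to 1.958), Hk1 (306.9 against 231.5 to 240.1) and Maats1 (0.1383 against 0.0337 to 0.0408). The Maats1 values are 4 reads against 1 in each other control, which counting error can give. Control replicate 3 stood apart for Ifi44 (7.523 CPM against 3.861 to 4.242), Nlrc5 (20.44 against 6.052 to 7.506) and the cell cycle score (0.83 against -0.093 to -0.048). Control replicate 2 stood apart for Plcb1 (10.97 CPM against 8.438 to 8.583) and control replicate 1 for the stress response score (-0.142 against -0.092 to -0.084). In KO, replicate 1 stood apart for gene reads (39.62 M against 26.59 to 28.81) and Ndufa5 (370.2 CPM against 282 to 290.4). KO replicate 3 stood apart for Myl1 (33.25 CPM against 23.45 to 24.66) and Mthfd2 (14.68 against 6.215 to 7.263). KO replicate 4 stood apart for Rps6ka2 (30.85 CPM against 36.41 to 37.11) and the branched-chain amino acid score (0.025 against -0.099 to -0.085).

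Camera at the preset correlation called a difference between males and females in the effect of genotype on 11 lists, and with an estimated correlation 0 of the 11 passed (adjusted p 0.793 to 0.969). At the preset correlation the adjusted p was 2.3e-07 for fatty acid oxidation (median -0.18 in males and 0.05 in females) and 2.3e-07 for immediate early genes (0.45 and -0.31). It was 7.345e-06 for the tricarboxylic acid cycle (-0.21 and 0.06), 9.578e-06 for branched-chain amino acid breakdown (-0.26 and -0.01) and 0.0002078 for calcium handling (-0.24 and 0.02). It was 0.0002078 for conduction markers, 0.001165 for cell cycle, 0.003865 for ER stress, 0.02346 for interferon, 0.02501 for mural markers and 0.03135 for cardiac ion channels. Each sex holds 2 libraries per genotype, and immediate early genes scored 0.634 in KO replicate 1 and -0.445 in KO replicate 4. Library numbers also set the genotypes apart within males, so an effect of library order is not separated from these differences.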

How the results depend on the processing

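The fit with the atrial score as a covariate and the fit without controls 3 and 4 together were chosen only after the data were seen. The cause of the changes below was not tested.

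The 15 genes between KO and control became 140 with DESeq2 (81 higher, 59 lower), 35 with limma voom with sample quality weights, 621 with no low count filter, 6 with no sex term, 30 at an adjusted p under 0.1, 37 with the atrial score as a covariate and 44 without controls 3 and 4 together. Without each library in turn the count ran from 0 to 50. It was 11 to 15 under limma voom, the other scalings, removal of mitochondrially encoded genes, the stricter filter and 1 surrogate variable. Of the 621 genes, 591 pass the filter and 30 do not. Without the filter the genes tested rose from 14695 to 27953 and the prior degrees of freedom of the edgeR fit from 5.22 to infinity. DESeq2 called all 15. With replicate number as a block the count was 0. With sex removed, same-number correlations ran from -0.51 to -0.22 and those of unlike numbers from -0.379 to 0.424. Removing sex itself lowers correlations within a sex. Without that step the ranges were -0.21 to 0.25 and -0.375 to 0.497. Libraries of the same number were thus no more alike than others, which gives no sign of pairing of animals but does not exclude it.

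The log2 fold change of Adgrf5 stayed under 0 and did not pass in any setting (-0.114 to -0.004). No genes named for KO against control reversed.

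The 13 lists became 0 with an estimated correlation, 0 with the directional fry test, 8 with 1 surrogate variable, 8 without controls 3 and 4 together (2 shared) and 8 to 15 without each library in turn. With 1 surrogate variable the mean log2 change went from -0.206 to -0.0308 for calcium handling (adjusted p = 0.309), from 0.085 to 0.0267 for oxidative phosphorylation (0.214) and from -0.124 to -0.0667 for branched-chain amino acid breakdown (0.0705), and the sarcomere and stress response lists did not pass (0.0705 each). With no filter Gq signalling passed (0.0394), while glycolysis (0.067), sarcomere (0.0866), p53 targets (0.0866) and lymphocyte markers (-0.298 to -0.0792, 0.145) did not. Cell cycle (0.101) and lymphocyte markers (0.155) did not pass with the stricter filter, nor lymphocyte markers with no sex term (0.137). With the atrial covariate calcium handling (0.126), sarcomere (0.075), oxidative phosphorylation (0.075) and p53 targets (0.0718) did not pass. Mean changes reversed for cell cycle (0.0124) and lymphocyte markers (0.0276) without controls 3 and 4 together. The adhesion receptor family reversed with no filter (0.0514), without controls 3 and 4 together (0.112) and in the leave-one-out fits (-0.0559 to 0.0657). Extracellular matrix reversed with the atrial covariate (0.00306) and in the leave-one-out fits (-0.171 to 0.00739).

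The 6 genes in males became 1007 with no filter, 329 with DESeq2, 78 with males alone and 0 to 59 without each library in turn. The 0 genes in females (edgeR, 753 at an unadjusted p under 0.05) became 277 with no filter, 16 with DESeq2 and 0 to 81 in the leave-one-out fits. The 0 genes of the interaction (edgeR, 1096 at an unadjusted p under 0.05) became 243, 18 and 0 to 8. The 44 genes between the sexes became 742, 210 and 16 to 176. In these fits a library alone in its sex and genotype is assumed to vary like the others.

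Among single genes and lists, uncalled ones included, alternatives fixed beforehand kept direction and side of the threshold 1844 times. They lost 225 calls, gained 41 and reversed 6 directions. The added ones gave 167, 18, 5 and 4. At this depth a count of 0 leaves a level of up to 0.118 CPM open in the smallest library.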

Other observations

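The tests of recombinase activity and of the spans of the called genes were chosen only after the result was seen.

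Cardiac ion channel genes moved both ways, and these members were chosen after their values were seen. Adjusted over the list alone, 2 members were higher in KO and 2 lower. The higher ones included Hcn2 (0.45, SE 0.0892, adjusted p = 0.0105). The lower ones were Kcnv2 (-0.89, SE 0.211, adjusted p = 0.0128) and Kcnd2 (-0.64, SE 0.188, adjusted p = 0.0389). Over all genes tested by edgeR the adjusted p of Hcn2, Kcnv2 and Kcnd2 was 0.132, 0.205 and 0.287, and the list as a set had a camera adjusted p of 0.986.

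Genes with long genomic spans tended to be lower in KO, where the median log2 fold change was 0.09 for 3320 genes under 10 kb and -0.16 for the 108 longest genes among those at 1 CPM or more. Of the 8 genes called lower 6 span at least 100 kb, against 13.6% of tested genes, but these genes prompted the pattern, so a test of their spans (Fisher exact p = 0.000137) restates it and decides nothing. Against short genes matched in mRNA length, GC content and expression, 643 long genes differed by -0.0839 (95% bootstrap interval -0.0998 to -0.0708), which argues against these biases as the whole cause. The interval resamples genes and leaves out the spread between animals. The difference was -0.148 in males and -0.0428 in females, which was not tested between the sexes, control replicate 3 (-0.048) lay below KO replicates 3 and 4 (-0.014 and -0.013), and 7 of the 34 estimable splits of the 8 libraries gave a matched difference as large (real -0.0839, farthest other -0.1105), so chance cannot be excluded. DNA damage by a recombinase may lower long transcripts and raise p53 targets, whose mean log2 fold change was 0.131, but it cannot be told apart from loss of the receptor, because the labels name no recombinase and do not say whether the controls, titled NLC and labelled wild-type, carry one.

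Adgrf5 was not lower in KO. Exchanging the labels of a KO and a control library of the same sex gave at most 6 called genes over 8 exchanges, against 15 with the labels as given. The count was unstable, at 0 to 50 without each library in turn. Exchanging all labels leaves it unchanged, so label errors are not excluded. The transcript may come mostly from cells other than cardiomyocytes, but the difference between Adgrf5 and the median endothelial marker, -0.00737, does not decide this, and the 2 cannot be told apart without values per cell type. A deletion of a few exons that leaves the rest of the transcript was not tested.

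Among the 34 estimable splits, only the real one (1 split) gave as many as 15 genes between KO and control. The highest other gave 6. Many of the other splits do not balance the sexes as the real one does, and the count was 0 without some single libraries. Chance is therefore not excluded for this count. Between the sexes, too, only the real one (1 split) gave as many as 44, with 17 as the highest other. Sex-linked genes made a sex difference certain beforehand, so this decides little. For gene lists, 12 splits gave at least the 13 of the real one, with 19 as the highest other, so chance cannot be excluded. For the mean log2 change of p53 targets in the linear fit, only the real split (1 split) reached 0.129, with 0.113 as the highest other. This list was picked from 41, however.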
